A study of Mus musculus with 2 samples.

How the data were processed

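Single-cell RNA sequencing was done on embryoid bodies, the aggregates in which mouse embryonic stem cells differentiate, made from EBRTcH3 cells that carry a construct for the intracellular domain of Odz4 (gene symbol Tenm4). Per the labels' protocols, the construct is under Tet-Off control, so that it is expressed when tetracycline (Tet) is taken away. The Tet- library came from cells from which Tet was removed on day 0, and the Tet+ library from cells kept in 1.1 µg/ml Tet until harvest. Bodies formed in hanging drops for 2 days and were harvested then or after 3, 5 or 7 more days. The cells of these harvests were pooled in each library, and no barcode carries a day, so each library was 1 sample. The series' design text differs, with culture with or without Tet from day 2 and a harvest at 3+5 in place of 2+5, and the protocol's wording is used here. Cells were put through the droplet-based 10x Chromium 5' chemistry, per the labels' protocols.

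The deposited matrices hold whole-number UMI counts per gene and barcode, with no normalization. Per the file headers and the submitters' processing notes, the authors made these counts with Cell Ranger 7.1.0, on the mm10 build. Filters used after barcodes had been called as cells are not given in the sources used here. Both libraries list the same 32285 genes. No feature named for the construct or a reporter was found under the names searched, and which part of Tenm4 the construct's reads cover is not given in the sources used here. The Tet- library held 9809 barcodes with 217742300 UMIs, a median of 20717 per barcode, and the Tet+ library 9172 barcodes with 228217282 UMIs, a median of 23909.

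Barcodes with at least 1000 detected genes and at most 10% mitochondrial UMIs were kept, which left 9033 and 8383. Scrublet, run through scanpy, marked 0 and 1 doublets at its automatic threshold and so had not worked here. Doublets were therefore removed by rank of the Scrublet score, at 0.8% per 1000 barcodes, which took 770 and 673 barcodes before the other filters. The 8276 Tet- and 7719 Tet+ cells that remained held 190437664 and 202468299 UMIs, with medians of 21194.5 and 24676 per cell. Counts were scaled to 10000 per cell and log-transformed, and 3000 variable genes were chosen over both libraries. Mitochondrial, ribosomal protein, sinoatrial, working chamber, and teneurin and latrophilin genes were left out of that choice, so that these lists could be compared inside a cluster. Clusters came from 40 principal components, 15 exact nearest neighbours and Leiden resolution 1, with no integration of the libraries.

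Clusters were named "X-like" from 25 marker lists, where at least 3 markers of a list stood among the 100 genes with the highest fold over all other cells (5 per 1000000 UMIs added). A cluster under 20 cells, or with more markers of other lists than of its own among its first 10 genes, stayed unnamed and was compared by number. Clusters 14, 15 and 17 had few UMIs per cell and stayed unnamed. The marker lists, cell filters, comparison lists and sizes that count were fixed before the data were examined. The details of the naming rule, and exact in place of approximate neighbours, were settled after first clusters had been seen.

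UMIs were summed per library over all cells and over each cluster, and given per 1000000 UMIs of that sum (CPM). Values are log2 ratios of CPM, Tet- over Tet+, so that a positive value is higher without Tet. Intervals are 95%: exact Poisson for a CPM, exact conditional binomial for a ratio, exact Clopper-Pearson for a share of cells, and 1000 Poisson resamples for a list's median. All of them cover counting error only, not the spread between cells or cultures. With 1 library per group there was no test across libraries, and no p-value, standard error or count of changed genes was made from cells.

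There were 22 comparison lists. A member with at least 20 UMIs in both libraries together was measured, and was called higher or lower at an absolute log2 ratio of at least 1, otherwise within 2-fold. A count of 0 in 1 library was set to 3 counts for a list's median. Each median was given a percentile among 10000 random lists of the same size matched on mean expression, as a description of these libraries. Where 2 gene identifiers share a symbol (Ddit3, Aldoa), the one with more UMIs was used, which was settled after a first run had picked the near-empty copy. Beyond list members, the rule named up to 10 higher and 10 lower genes in each population. These were ranked by the interval bound nearest 0 among genes with at least 100 UMIs and a ratio of at least 1. Gene models, mitochondrial and ribosomal protein genes were left out of that ranking.

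For shares of cells with a UMI, each cell was thinned at random to 3000 UMIs. That left out 243 Tet- and 175 Tet+ cells with fewer. Shares at 2000 UMIs and without thinning were alternatives. Cells with at least 30 globin UMIs of these 3000 were called globin-rich, and their other blood genes were compared after the whole-library values had been seen. Gene positions, GC content, transcript length and shared 31-base words came from the GENCODE vM21 annotation of GRCm38, the assembly that mm10 names, in which 32235 of the features had a position and 32158 a transcript. The ratio, interval and list code was tested on simulated data with 200 changed genes per population. The simulated counts were Poisson draws with no spread between cells or cultures, which is the error that the intervals assume. The rates that follow therefore check the code and are not error rates for these libraries. For the whole library (17149 genes), 100% of genes set at a log2 ratio of 1.5 were called, 0% of unchanged genes were, and 94.2% of intervals covered the true value. For cluster 0 (10584 genes) these were 98.9%, 0% and 95.5%, and for cluster 18 (2319 genes) 98.9%, 0.047% and 95.7%.

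Alternatives fixed in advance were 3 other cell filters, no or automatic doublet removal, TMM (edgeR 4.0.16) and median-of-ratios (DESeq2 1.42.0) scaling, CPM without mitochondrial and ribosomal protein genes, and the mean over cells in place of sums. Others were other count minimums, thinning, 2 other Leiden resolutions, 20 components, variable genes with the lists, and a class defined by 4 of 6 sarcomere genes. Equal cluster weights (each cluster given its mean share as weight in both libraries), approximate neighbours, and leaving out the clusters with few UMIs or the erythroid-like cluster were added after seeing the data. The work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9, and in R 4.3.3.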

Results

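Gene expression was measured in single cells of embryoid bodies that carried an inducible construct for the intracellular domain of Odz4 (Tenm4), a transmembrane protein of the teneurin family. The question named in the series' title is whether this domain raises genes of the sinoatrial node, the pacemaker of the heart, during differentiation. Per the labels' protocol, tetracycline was withdrawn on day 0 for the Tet- library, so that the domain would be expressed, and kept at 1.1 µg/ml for the Tet+ library, while the series' design text speaks of culture with or without it from day 2. Expression of the domain itself was not measured. Each group had 1 library, so none of the differences has a replicate check. The 8276 Tet- cells held 190437664 UMIs and the 7719 Tet+ cells 202468299, with medians of 21194.5 and 24676 UMIs per cell. All ratios are log2 ratios of CPM (UMIs of a gene per 1000000 UMIs), Tet- over Tet+, with 95% counting intervals that leave out the spread between cells and cultures.

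Tenm4 (ENSMUSG00000048078, chromosome 7, 96171246 to 96911093, plus strand, GRCm38) had 22293 UMIs in the Tet- library and 14062 in the Tet+ library. Its CPM of 117.1 against 69.5 gave a log2 ratio of 0.75 (0.72 to 0.78). Of the 12 clusters with at least 200 cells in each library, 11 had a higher Tenm4 CPM in the Tet- library, each with an interval above 0. The ratio was 2.26 in cluster 6, led by Tubb3 and Igfbp5, 1.48 in cluster 4, led by Htra1 and Gas6, 1.35 in cluster 7 and 0.78 in pluripotent-like cells. It was smaller in the clusters with most Tenm4 UMIs, at 0.30 in cluster 5 (24.1% of the UMIs), 0.36 in cluster 3 (19.5%) and 0.14 in primitive streak-like cells (17.7%). The order differed for the CPM difference, Tet- minus Tet+. That was 51.6 in cluster 5, 52.4 in cluster 3 and 14.5 in primitive streak-like cells. It was 70.4 in cluster 6, 39.1 in cluster 4, 18.4 in cluster 7 and 5.47 in pluripotent-like cells. The ratio was also small in epiblast-like (0.36) and mesenchyme-like cells (0.23), cluster 9 (0.38) and cluster 16 (0.31). In definitive endoderm-like cells it was -0.09 (-0.36 to 0.18). In the smaller endothelium-like cluster it was 2.62 (96 against 26 UMIs). It was 3.41 in the erythroid-like cluster, where Krt8 (3.82) and Msx1 (3.34), genes of other cell types, were higher as well. Reads of the construct may not all count towards Tenm4, so this value checks the labels only in part. With each cluster given the same weight in both libraries, a choice made after seeing the data, the whole-library ratio was 0.45. Values named below as having the same cluster weights were made in this way.

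**Figure D1:**
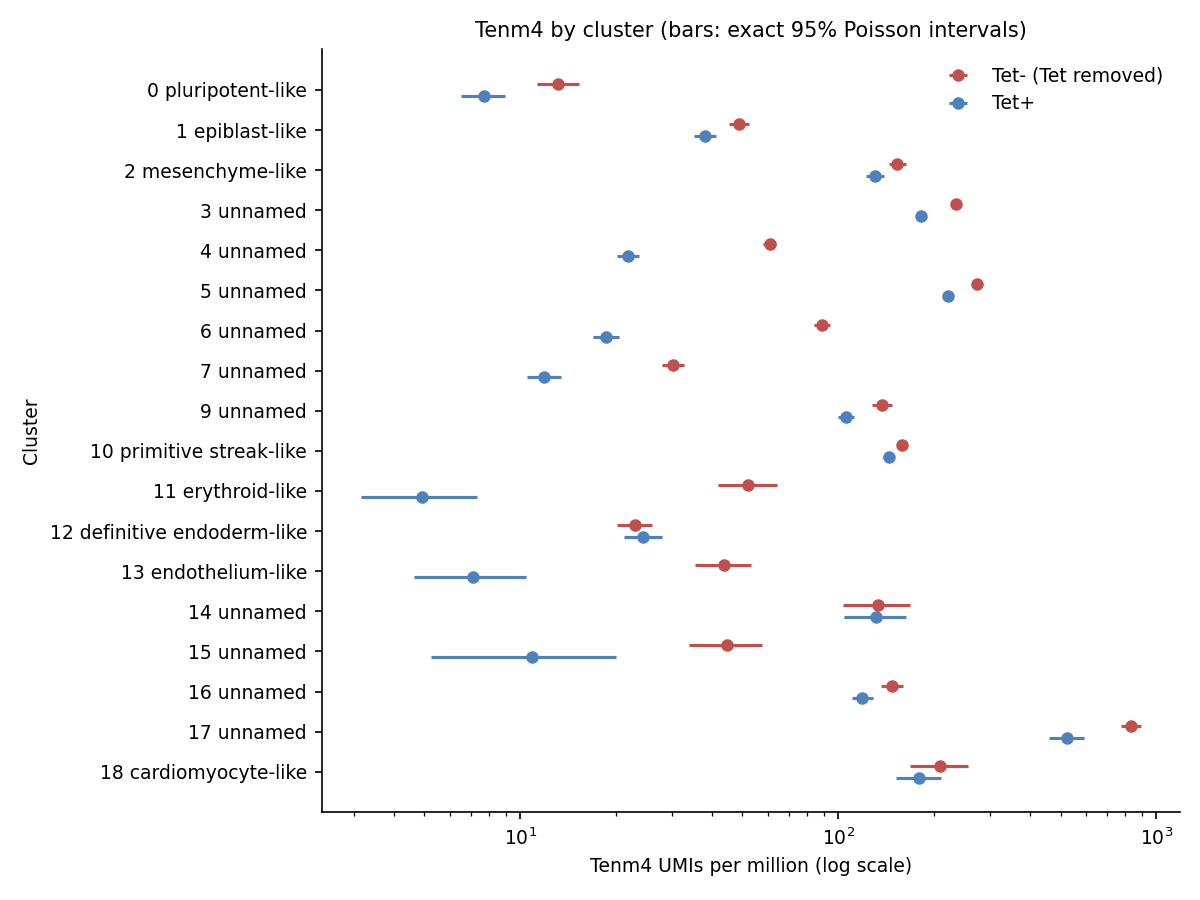
Tenm4 CPM (log axis) in each cluster of the Tet- (red) and Tet+ (blue) libraries, 1 library per group, with exact 95% Poisson intervals as bars. The Tet- value lies above the Tet+ value in 11 of the 12 clusters with at least 200 cells in each library, the exception being the definitive endoderm-like cluster.

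Genes of the sinoatrial list had slightly higher CPM in the Tet- library as a whole. The median log2 ratio of its 22 members was 0.20 (0.12 to 0.31), at percentile 100 of 10000 matched random lists as a description of these libraries, and 19 members had a ratio above 0. Hcn1 (chromosome 13, 117602320 to 117987418), a pacemaker current channel, was the 1 member beyond 2-fold, with 2270 against 1104 UMIs and a ratio of 1.13 (1.02 to 1.23). It was at 0.80, within 2-fold, with the same cluster weights. Smoc2, a secreted matrix protein, had a ratio of 0.86 (0.80 to 0.92) and Hcn2 of 0.78 (0.56 to 0.99). Hcn4 (chromosome 9, 58823412 to 58863175), the main pacemaker channel of the node, had 245 against 186 UMIs and a ratio of 0.49 (0.20 to 0.77). The transcription factors of the list were at 0.43 for Tbx5, 0.33 for Tbx3, 0.14 for Tbx18, 0.11 for Shox2 and 0.02 for Isl1. The calcium channel gene Cacna1d was at -0.23 (-0.35 to -0.11). Lists of other kinds had whole-library medians of like size, such as BMP targets (0.22) and feeder and fibroblast genes (0.26). Others were below 0, such as the endothelial (-0.59) and pluripotency lists (-0.28). The size of the sinoatrial median was thus not particular to that list.

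Most UMIs of Hcn1 and Hcn4 came from cells other than cardiomyocyte-like ones. Cluster 5, which was led by Ptn, Tbx4, Hcn1 and Kcnk3, held 48.8% of the Hcn1 UMIs, at 56.2 CPM in the Tet- and 33.8 CPM in the Tet+ library, a ratio of 0.74 (0.58 to 0.89). The cardiomyocyte-like cluster had 55.6 and 41.2 CPM of Hcn1. In cluster 3, led by Tbx4, Ptn and Pitx1, the Hcn1 ratio was 0.82 (0.63 to 1.01), that of Smoc2 was 1.52, and Hcn4 had 57 against 26 UMIs, a ratio of 1.06 (0.37 to 1.79). In cluster 3, 11 of 750 Tet- and 0 of 596 Tet+ cells had an Hcn4 UMI at 3000 UMIs per cell (the 0 allows up to 0.617%), 4 of 752 and 3 of 597 at 2000, and 50 of 752 and 24 of 597 without thinning. In cluster 5, which held 24.4% of the Hcn4 UMIs, the Hcn4 ratio was 0.58 (-0.03 to 1.23). Hcn4 had its highest level in the cardiomyocyte-like cluster, which held 10.4% of its UMIs. That was the largest part for any member of the sinoatrial list, with 0.12% for Tbx3 and 0.40% for Bmp4. At 3000 UMIs per cell, 3.45% (3.06 to 3.87) of 8033 Tet- cells and 1.63% (1.36 to 1.94) of 7544 Tet+ cells had an Hcn1 UMI, and 0.510% (0.367 to 0.692) and 0.225% (0.131 to 0.361) an Hcn4 UMI. At 2000 UMIs per cell the Hcn4 shares were closer, 0.305% (0.197 to 0.450) and 0.248% (0.149 to 0.386). In pluripotent-like cells, which should lack both genes, 0 of 572 and 0 of 795 had either, which allows shares of up to 0.643% and 0.463%, above the Hcn4 shares. Those cells had median depths of 21656 and 24339 UMIs. Without thinning, 12.6% and 7.25% of all cells had an Hcn1 UMI, against 1.20% and 1.11% of pluripotent-like cells. An Hcn4 UMI was in 2.60% and 2.01% of all cells, against 0.172% (up to 0.955%) and 0.123% (up to 0.685%) of pluripotent-like cells. With the same cluster weights the median of the list was 0.092, and it was 0.37 when cells were thinned.

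**Figure D2:**
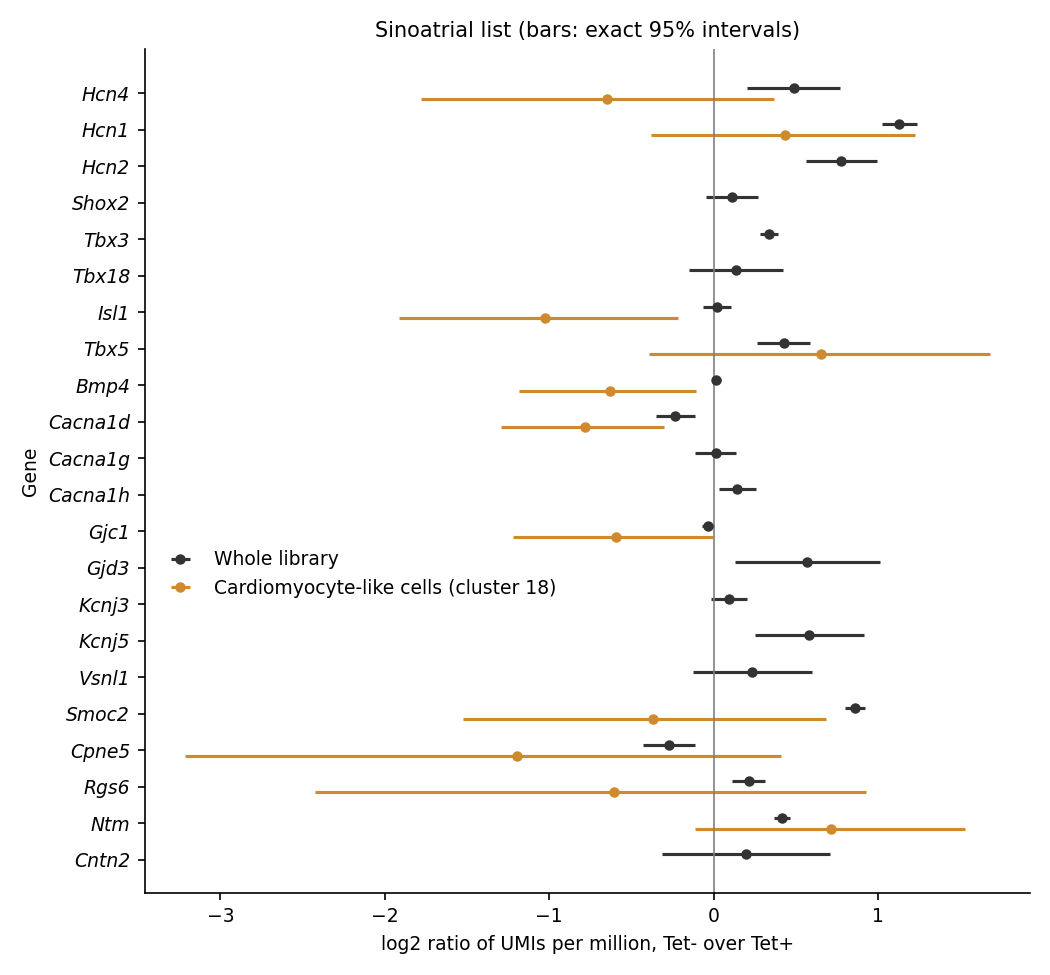
Log2 ratio of CPM, Tet- over Tet+, for each measured sinoatrial list gene in the whole library (black) and in the cardiomyocyte-like cluster (orange), with exact 95% counting intervals. In the whole library 19 of the 22 genes lie above 0, while in the cardiomyocyte-like cluster 3 of the 11 measured genes do.

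With the clustering used here, cardiomyocyte-like cells (cluster 18) were few, with 26 of 8276 Tet- cells, 0.314% (0.205 to 0.460), and 39 of 7719 Tet+ cells, 0.505% (0.360 to 0.690). These intervals do not cover the choice of clustering, on which the size of the class depended, as given below. The log2 ratio of the shares was -0.69 (-1.46 to 0.07). No direction is given for this share, because 4 of the 10 genes that lead the cluster differed more than 2-fold between the libraries within it. Inside the cluster the sinoatrial list had a median of -0.61 (-0.88 to -0.16), at percentile 0.45 of matched random lists, with 2 of 11 measured members lower and none higher. Isl1 had 16 against 64 UMIs, a ratio of -1.02 (-1.91 to -0.22), and Cacna1d 46 against 156 UMIs, -0.79 (-1.29 to -0.30). Hcn4 had 11 against 34 UMIs, -0.65 (-1.78 to 0.36), and Hcn1 24 against 35, 0.43 (-0.38 to 1.22), so that neither differed detectably at this depth. At 3000 UMIs per cell, 3 of 25 and 4 of 38 cells had an Hcn4 UMI. The working chamber list, genes of contracting heart muscle such as Nkx2-5 (0.09) and Gja1 (0.29), had a median of 0.09 (-0.29 to 0.54) over 5 measured members, at percentile 66.25. The sarcomere list, whose genes helped to define the cluster, was at -0.56 (-0.86 to -0.45), percentile 0, with 16 of 17 members below 0 and 5 lower, namely Myh6 (54 against 706 UMIs, -2.73), Actn2 (-1.55), Myl7 (630 against 3178 UMIs, -1.36), Myh7 (-1.17) and Ttn (-1.01). The lower sinoatrial median was therefore not particular to that list. The calcium handling list was at -0.16 and cardiac transcription factors at 0.22.

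The size and content of this class depended on the clustering. At Leiden resolution 2 it held 535 and 461 cells with a share ratio of 0.11, and with 20 components 643 and 562 cells with a ratio of 0.094. Its sinoatrial median was then -0.17 and -0.14. Over all 19 alternatives that median ran from -1.51 (when cells were thinned) to 0.06, and the working chamber median from -0.42 to 0.17 over 18. Thinning left few UMIs in this class, so the value of -1.51 rests on few members of the list. Cells with UMIs of at least 4 of 6 sarcomere genes, a range rather than a type, numbered 55 in the Tet- (0.665%) and 70 in the Tet+ library (0.907%), while 166 and 221 cells had UMIs of 3. Of the cells with at least 4, 44 were in cluster 18 and 43 in cluster 7, which was led by Rbp4, Acta1, Ttr and Nppb.

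Over whole libraries, heart muscle genes had mixed values. The sarcomere list had a median of -0.033 (-0.22 to -0.015), and 2 of its 17 members were lower, namely Myh6 (710 against 1620 UMIs, -1.10) and Ttn (960 against 2406 UMIs, -1.24). With the same cluster weights Myh6 was at -1.01 and Ttn at -0.71, within 2-fold, and the list median was 0.026. The cardiomyocyte-like cells of cluster 18 held 66.3% of the Ttn and 32.6% of the Myh6 UMIs, so both values rest in part on few cells. Myh7, with 73.1% of its UMIs in cluster 7, was at -0.65, and Tnnc1 was at 0.38. Without thinning, Epcam of the definitive endoderm list was in 89.7% of Tet- and 88.0% of Tet+ cells of cluster 7. Tnnc1 was in 67.4% and 68.9% of them, but Tnnt2 in 10.8% and 10.5%, against 92.3% and 89.7% in cardiomyocyte-like cells. The Myh7 value thus comes mostly from cells not named cardiomyocyte-like. The calcium handling list had a median of 0.02 and the working chamber list of 0.04 (-0.055 with the same cluster weights), with no member of either beyond 2-fold. Cardiac transcription factors had a median of 0.20 (0.18 to 0.24), percentile 99.99, with Gata4 at 0.53 and Gata6 at 0.49. Mesp1, which marks early heart mesoderm, was at 0.67, but at -0.14 with the same cluster weights.

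Blood genes were far lower in the Tet- library. All 12 members of the list had a ratio below 0, 10 of them were lower by the 2-fold rule, and the median was -2.32 (-2.54 to -2.15), at percentile 0. With the same cluster weights the median was -1.67, Gata1 (-0.84), Lyl1 (-0.63) and Tal1 (-0.19) were within 2-fold, and Itga2b was at 0.16. Among the list members the embryonic globins Hbb-bh1 and Hba-x differed most, with 3096 against 71246 UMIs of Hbb-bh1 (-4.44) and 8779 against 178202 of Hba-x (-4.25). The erythroid factors Klf1 (-2.55; -2.92 to -2.19) and Gata1 (-1.96; -2.18 to -1.75) and the red cell membrane protein gene Gypa (-3.57) were lower too. Runx1, needed for the first blood stem cells, was at -0.22 and Itga2b at -0.56, both within 2-fold. With each cell thinned to 3000 UMIs, 0.162% (0.086 to 0.277) of Tet- and 2.27% (1.94 to 2.63) of Tet+ cells had at least 30 globin UMIs. Outside the erythroid-like cluster globins made up 0.837 and 40.3 CPM, unevenly, with Hba-x in the Tet+ library at 1.21 CPM in epiblast-like, 82.8 CPM in cluster 7 and 418 CPM in endothelium-like cells. The erythroid-like cluster held 87 and 251 cells, with 10236 and 62902 CPM of globin. Of its cells with at least 3000 UMIs, 15.3% (8.40 to 24.7) of the Tet- and 65.6% (59.4 to 71.5) of the Tet+ cells had at least 30 globin UMIs. Genes of other cell types were higher there in the Tet- library as well, as given above for Krt8 and Msx1. Whether the cluster held unlike cells in the 2 libraries, or like cells with less globin RNA, was not tested. The shares of the cluster, 1.05% and 3.25%, are given without a direction, since 7 of its 10 leading genes differed more than 2-fold.

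**Figure D3:**
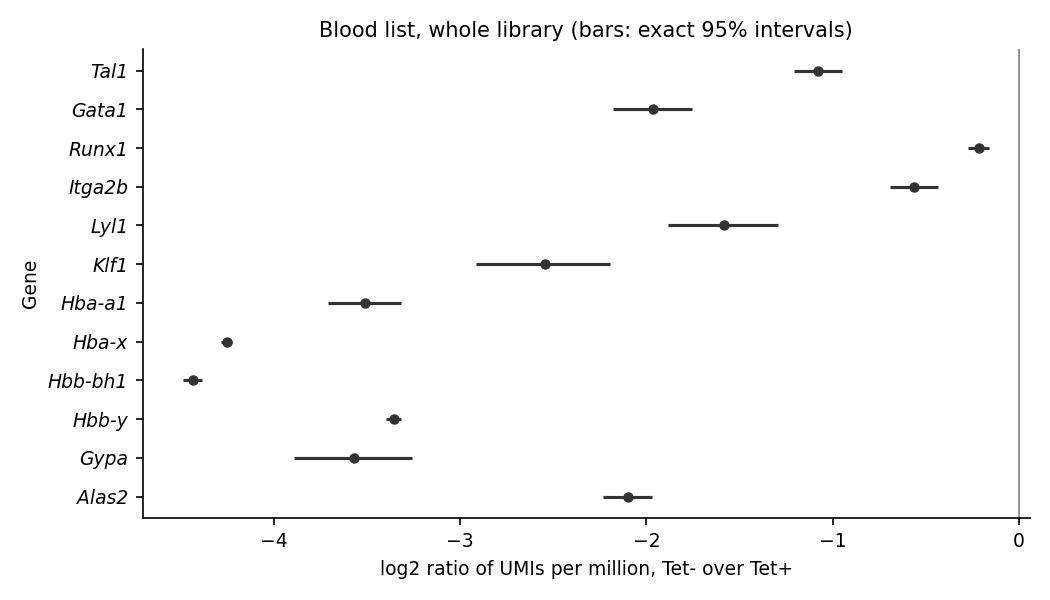
Log2 ratio of CPM, Tet- over Tet+, for each of the 12 blood list genes in the whole library, 1 library per group, with exact 95% counting intervals as bars. All 12 lie below 0, from -0.22 for Runx1 to -4.44 for Hbb-bh1.

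The endothelial list had a whole-library median of -0.59 (-0.67 to -0.51), percentile 0, with 8 of 10 members below 0 and all within 2-fold. With the same cluster weights it was -0.010. Erg was at -0.87, Tek at -0.80 and Pecam1 at -0.72, whereas Kdr and Etv2, which also mark earlier mesoderm, were at 0.33 and 0.32. Endothelium-like cells made up 1.39% (1.15 to 1.67) of the Tet- and 1.94% (1.65 to 2.28) of the Tet+ library, and none of the genes leading their cluster differed more than 2-fold. Pluripotent-like cells made up 7.02% (6.48 to 7.59) and 10.5% (9.83 to 11.2), a log2 ratio of -0.58. Definitive endoderm-like cells made up 5.49% and 4.48%, a ratio of 0.29 (0.09 to 0.50). Mesenchyme-like cells made up 5.87% and 6.04% (-0.04), but the ratio was 0.80 at Leiden resolution 2 and 0.51 with the wider cell filter. Cluster 6 made up 4.56% and 8.46% (-0.89), cluster 3 9.09% and 7.73% (0.23), cluster 7 8.94% and 7.99% (0.16) and cluster 16, led by Mecom and Mab21l2, 2.63% and 3.69% (-0.49). Primitive streak-like cells made up 13.1% and 7.36%, cluster 5 13.0% and 7.49%, and cluster 9, led by Tdo2 and Hsd11b2, 3.49% and 7.01%. No direction is given for these, because 1 or 2 of their leading genes differed more than 2-fold. Each library pooled bodies of several culture days in unknown parts, so shares can be set by the pooling.

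**Figure D4:**
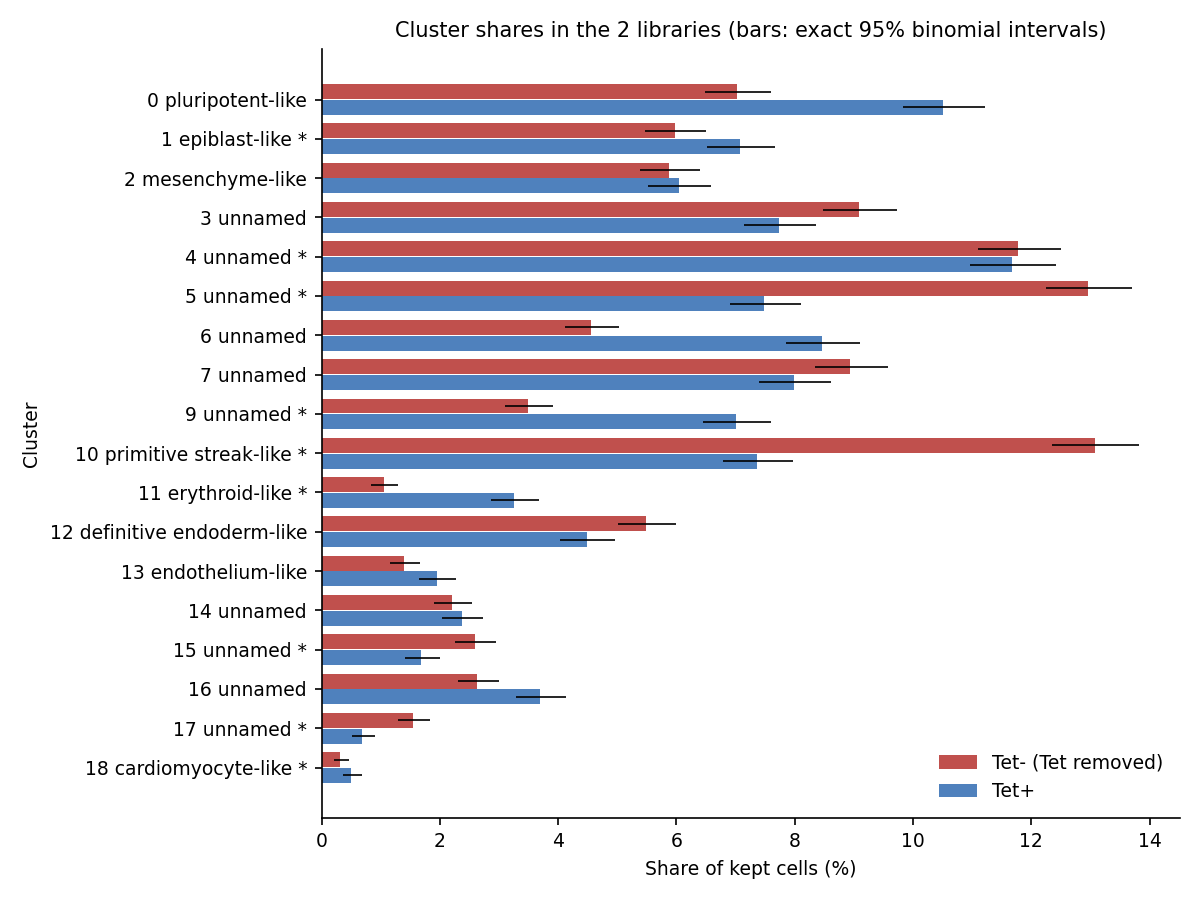
Share of kept cells in each cluster (percent) in the Tet- (red) and Tet+ (blue) library, with exact 95% binomial intervals. An asterisk marks clusters with at least 1 leading gene more than 2-fold apart between the libraries, for which no direction is given, and the pluripotent-like share is 7.02% against 10.5%.

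Genes of early fates and signals differed less than those of blood. The pluripotency list had a median of -0.28 (-0.30 to -0.26), percentile 0, with Pou5f1 at -0.28 and Nanog at -0.35, while Klf4 was at 0.68. Of the Klf4 UMIs, 4.30% were in pluripotent-like cells, where its ratio was 1.05, and 25.6% were in cluster 4. With the same cluster weights the median of the pluripotency list was 0.044. The mesendoderm list had a median of 0.20 (0.14 to 0.26), with Lhx1 at 0.61 and T at -0.53. With the same cluster weights its median was -0.21, with Lhx1 at -0.026 and T at -1.15. BMP targets had a median of 0.22 (0.18 to 0.25), percentile 100, with Msx1 at 0.82 and Id1 at 0.45. Wnt targets were at 0.21, with Sp5 at 0.59, but at 0.12 and 0.10 with the same cluster weights. Notch targets were at 0.19 (0.073 with the same weights), with Hes5 at 0.82. The neural list was at 0.09, the visceral endoderm list at 0.12 (0.24 with the same weights), with Afp at 0.72, and the teneurin and latrophilin list, which holds Tenm4, at 0.10. The feeder and fibroblast list was at 0.26, with Lox at 0.85. No member of these lists was beyond 2-fold in the whole library. With the same cluster weights T was, as was S100a4 of the feeder and fibroblast list (1.38).

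By cluster, BMP targets were highest relative to the Tet+ library in pluripotent-like cells, among clusters with at least 200 cells in each library. Their median there was 0.70 (0.53 to 0.81), with Id1 (384 against 214 UMIs) at 1.46 and Id2 at 1.11. In primitive streak-like cells the median was 0.60, with Msx1 at 0.80, and the mesoderm factors Hand1 (7669 against 1634 UMIs) and Hand2 were at 1.39 and 1.02. In the same cluster Hoxb6 was at 2.95, Hoxb8 at 2.51 and the R-spondin receptor gene Lgr5 at 1.91, while Pou5f1 was at -1.40 and Nanog at -1.95. Of the 10 genes leading this cluster, 2 differed more than 2-fold between the libraries, and the median of the 10 was -0.48. The values in this cluster may therefore come from unlike cells in the 2 libraries, which was not tested. In definitive endoderm-like cells the sinoatrial list had a median of 0.56 (0.19 to 0.76), with Isl1 (142 against 63 UMIs) at 0.93, and Wnt targets of 0.55, with Cdx2 at 1.83 and Dkk1 at 1.32. In cluster 5 the feeder and fibroblast list had a median of 0.65 (0.53 to 0.91), with the collagen-binding proteoglycan gene Lum (1677 against 345 UMIs) at 1.68.

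The integrated stress response list, genes of amino acid shortage and protein folding stress, had a whole-library median of 0.17 (0.14 to 0.19), and its values differed by cluster. In cluster 9 the median was 1.51 (1.41 to 1.58), with 8 of 11 measured members higher, among them Asns (1398 against 892 UMIs, 1.81), which makes asparagine, and Trib3 (2.94). In cluster 6 it was 1.05 (0.97 to 1.14), with 7 of 12 higher, including Asns at 1.52 and the serine synthesis gene Phgdh at 1.43. It was 0.83 in cluster 7 and 1.10 (0.70 to 1.34) in cardiomyocyte-like cells. In definitive endoderm-like, epiblast-like and pluripotent-like cells it was -0.39, -0.33 and -0.17. Among the higher members of both clusters, Asns, Phgdh and Shmt2 are enzymes of amino acid and one-carbon metabolism. The RNA of Atf4, the factor that drives them, was at -0.56 in cluster 6 and -0.13 in cluster 9, and that of Ddit3 at -0.28 and 0.33. Protein levels of these factors were not measured. Of the 10 leading genes, 1 of cluster 9 and 0 of cluster 6 differed more than 2-fold between the libraries. The standard deviation of the log2 ratio over genes with at least 100 UMIs was 0.40 in cluster 6 and 0.39 in cluster 9. No other cluster with at least 200 cells in each library had a wider spread. Whether the values in clusters 6 and 9 come from unlike cells in each library was not tested. The genes named by rule in these clusters included the amino acid transporter gene Slc7a3 at 2.83 in cluster 6 and 3.53 in cluster 9, the serine synthesis gene Psph at 2.35 and 2.11, and Cth, which makes cysteine, at 1.98 and 2.63. In cluster 9 the collagen gene Col1a1 (257 against 1815 UMIs) was at -1.66 and the lactate transporter gene Slc16a3 at -2.03.

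**Figure D5:**
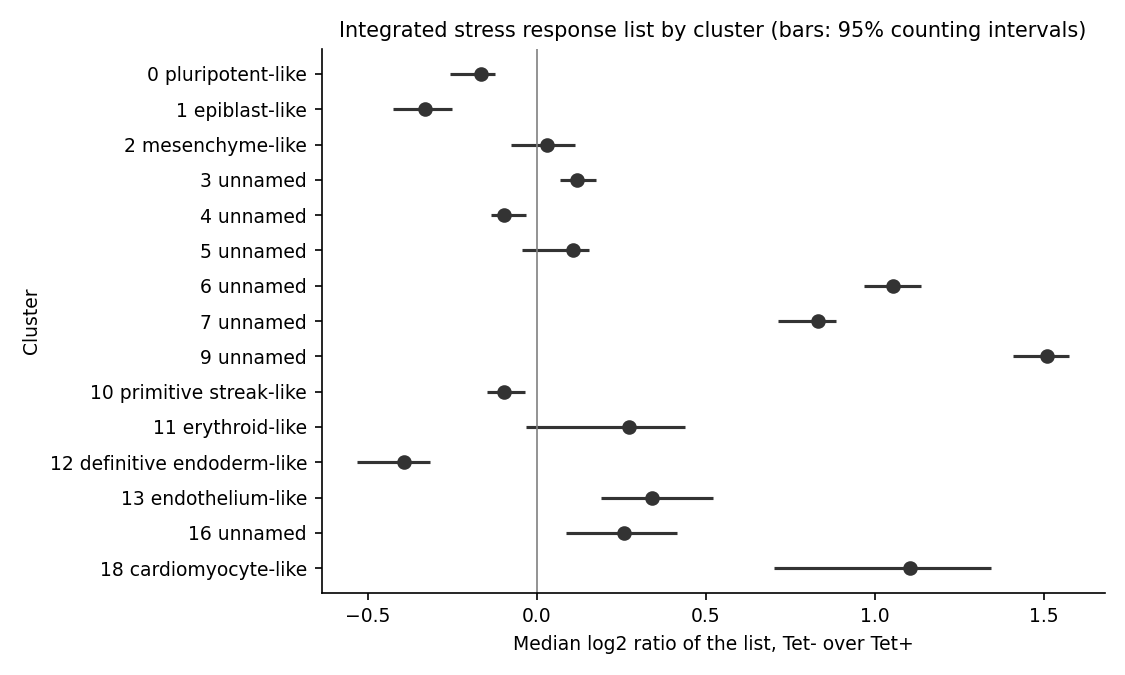
Median log2 ratio, Tet- over Tet+, of the measured integrated stress response list genes in each cluster, with 95% counting intervals as bars. The medians run from -0.39 in the definitive endoderm-like cluster to 1.51 in cluster 9, where 1 of the 10 leading genes differed more than 2-fold between the libraries.

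Lists that report on growth and handling of the cells had no member beyond 2-fold. G2/M phase genes had a whole-library median of -0.20 (-0.21 to -0.18) with all 14 below 0, and were at -0.63 in clusters 6 and 9. S phase genes were at -0.10 and hypoxia and glycolysis genes at -0.07 (0.046 with the same cluster weights). Genes encoded by the mitochondrial genome were at -0.22 (-0.23 to -0.20). Immediate early genes, which dissociation of tissue induces, were at 0.29 (0.26 to 0.31) with all 11 above 0 and Fos at 0.44, and their median lay above 0 in each of the 12 clusters with at least 200 cells in each library.

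By the rule for single genes, those higher in the Tet- library included Minar1 (1662 against 193 UMIs, 3.19; 2.98 to 3.42), the protein kinase C gene Prkcb (3523 against 861 UMIs, 2.12; 2.01 to 2.23) and Wtip (9393 against 2843 UMIs, 1.81). Rab39 (1.93), the nephron progenitor factor gene Six2 (1.73), the AP-1 repressor gene Jdp2 (1.59), Ptprr (2.17), the chemokine gene Cxcl13 (2.71), Ofcc1 (3.45) and AC103362.1 (3.24) made up the rest of the 10. Prkcb was at 4.46 in pluripotent-like (950 against 66 UMIs) and 3.00 in epiblast-like cells, and Minar1 at 3.87 in mesenchyme-like cells and 4.26 in cluster 4. The 10 lower genes were mostly of red cells, with Hbb-bs (-4.28), Hba-a1 (-3.51), Hbb-y (-3.36), the Kell blood group gene Kel (-4.41) and Trim10 (-3.65) beside those above. Hao1 (10 against 253 UMIs) was at -4.57 and BC048559 (49 against 528 UMIs) at -3.34. In pluripotent-like cells Agbl1 had 1 against 228 UMIs, a ratio of -7.22. TMM, median-of-ratios and CPM without mitochondrial and ribosomal genes moved the median of all genes by at most 0.006 in the whole library and 0.024 in cardiomyocyte-like cells.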

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

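Both results here were picked by a rule on opposite signs between clusters, applied after the values had been seen, and neither difference was tested.

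The mesendoderm list had a median log2 ratio (Tet- over Tet+) of 1.86 (0.40 to 2.48) in cluster 16, over 5 measured genes with few UMIs, such as Eomes with 23 against 6. In primitive streak-like cells, a cluster that genes of this list define, it was -0.48 (-0.54 to -0.41) over 10 genes, a difference of 2.34.

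The integrated stress response list was at 1.51 (1.41 to 1.58) in cluster 9 and at -0.39 (-0.53 to -0.32) in definitive endoderm-like cells, over 11 genes in each, a difference of 1.90.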

How the results depend on the processing

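Equal cluster weights (each cluster given the same weight in both libraries), approximate neighbours, and leaving out the clusters with few UMIs or the erythroid-like cluster were chosen after seeing the data, and the other alternatives before. No test across libraries and no paired analysis was possible, because each group has 1 library. The cause of each move below was not tested. The Tenm4 ratio of 0.75 was positive under all 13 alternatives, and left its counting interval with the mean over cells (0.80), thinning to 3000 UMIs (0.87) and equal cluster weights (0.45). The whole-library sinoatrial median of 0.20 was positive under all 16, and left its interval with thinning (0.37) and equal weights (0.092). The cardiomyocyte-like share ratio of -0.69 ran from -1.10 to 0.11 over 11 alternatives, 9 of them inside its interval, and left it at Leiden resolution 2 (0.11) and with 20 components (0.094).

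The sinoatrial median in cardiomyocyte-like cells, -0.61, stayed inside its interval under 12 of 19 alternatives and was below 0 under 18. It was 0.065 with at least 500 genes and at most 20% mitochondrial UMIs, -0.055 with at least 2000 genes and at most 5%, and -0.062 at the automatic Scrublet threshold. It was -0.015 at Leiden resolution 0.5, -0.14 with 20 components, -0.088 with approximate neighbours and -1.51 when thinned. These settings, thinning apart, also changed how many cells the class held, from 26 and 39 cells to, for example, 669 and 1185 at Leiden resolution 0.5. The working chamber median in those cells, 0.09, had the other sign under 6 of 18 alternatives, and left its interval with the class defined by at least 4 of 6 sarcomere genes (-0.42). No member of that list was left to measure after thinning. The sinoatrial list was sparse there as well, with Isl1 in 1 of 25 Tet- and 9 of 38 Tet+ cells and Hcn4 in 3 and 4. Its median of -1.51 after thinning therefore rests on few members. For the shares of the other named classes, 29 of 34 values stayed inside the interval and 2 had the other sign. With equal cluster weights, 8 of the 21 other whole-library lists stayed inside their intervals and 5 had the other sign, namely working chamber, sarcomere, pluripotency, mesendoderm, and hypoxia and glycolysis. The 3 other scalings shift all genes of a library alike and so say little about stability. The log2 ratio of the share of cells with an Hcn4 UMI was 1.18 at 3000 UMIs, 0.30 at 2000 and 0.37 without thinning. Among the clusters in which lists were compared, depth limits the cardiomyocyte-like one most, where 431485 and 848924 UMIs left 2319 genes with at least 100.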

Other observations

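The tests inside globin-rich cells, of the mix of days, of the cardiomyocyte-like source of Hcn1 and of shared copies were chosen after the results they bear on had been seen, and the others before. The test inside globin-rich cells first asked only for a median near 0, which its value of 0.039 met, and the condition that each gene be within 2-fold was added once the single values were known. The rule set in advance for the erythroid-like share would have counted -1.67 against it. It was set aside after the cluster was seen to hold unlike parts of globin-rich cells.

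In pluripotent-like cells the sarcomere list had a median log2 ratio of 1.06 (0.58 to 1.38), with 8 of 15 measured members higher, but a few cells carried most of these UMIs. Of the 435 Tet- UMIs of those 8 genes, 5 of 581 cells held 70.6%, and the 45 Tnnt2 UMIs (against 3) all came from 5 cells, with 3 of 811 cells having one in the Tet+ library. Without the 5 cells of each library with the most such UMIs, a step added after seeing the data that by itself lowers these genes, the median was 0.13 (-0.070 to 0.43) and no member was higher. The sarcomere value is thus not given as a change of the class. Cardiac transcription factors were less concentrated, at 1.10 (0.49 to 1.62) with 27.1% of the Tet- UMIs of the 5 higher genes in 5 cells, and without the top cells at 1.00 (0.19 to 1.56) with 3 members higher, on few UMIs (107 against 69 before). What these cells are was not tested. The visceral endoderm list was at 0.49 (0.30 to 0.54) in cluster 7, with Cubn (54 against 23 UMIs) at 1.22.

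A group of 14 genes, chosen after their values were seen, differed at least 2-fold in the same direction in each of the 12 clusters with at least 200 cells in each library. Named among them, Wtip (whole-library ratio 1.81), Rab39 (1.93), Ppp2cb (1.32), Sap30l (1.23) and Trim59 (1.17) were higher in the Tet- library and C9orf72 (chromosome 4, 35191285 to 35226175) was lower, at -2.63. The other 8 were gene models or pseudogenes, such as Gm10358 (7.88) and Gm40646 (-8.95). With the trends on GC content and transcript length removed, the median absolute ratio of the 14 was 1.93, against 1.94 before. The largest autosome median of the ratio with equal cluster weights was 0.0144, which argues against the gain or loss of a whole chromosome. Reads shared with near-identical copies are a candidate source of counts for the 5 gene models and pseudogenes of protein-coding biotype. Of their 31-base words, a median of 91.7% were in other genes. This overlap is the same for both libraries, so by itself it does not account for a difference between them. The values argue against such reads from other annotated transcripts for the 3 of other biotypes (median 6.14%, highest 13.0%, Gm40646 0%), a split made after the values were seen. The same holds for the 6 genes with other symbols (median 0%, highest 10.9% for Trim59). Tetracycline itself cannot be told apart from the construct, since 0 libraries lacked the construct, and an unlinked difference between the 2 cultures stays open as well.

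The lower blood list in the Tet- library goes with fewer globin-rich cells, those with at least 30 globin UMIs of 3000, which numbered 13 against 171. Inside these cells the 8 blood genes that are not globins had a median of 0.039 (-0.12 to 0.35), with Klf1 at -0.18 and Gypa at -0.16 but Runx1 at 1.82 and Itga2b at 1.66, so that fewer red cells of like content stay a candidate explanation that these 13 cells cannot decide. With equal cluster weights the list was at -1.67, but a lower share of erythroid-like cells cannot be told apart by this value, since the cluster held unlike parts of globin-rich cells (15.3% and 65.6%). An unequal mix of culture days between the libraries cannot be told apart from the construct, because no cell carries its day. The pluripotent-like share was lower in the Tet- library (-0.58). Primitive streak-like cells made up 13.1% of that library against 7.36%, but no direction is given for this share, since 2 of the cluster's leading genes differed more than 2-fold. An effect of the domain on blood formation stays open and was not tested.

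Of the Hcn1 excess of the Tet- library, cluster 5 gave 60.3%, cluster 3 gave 27.0% and the cardiomyocyte-like cluster -0.72%. The cardiomyocyte-like cluster held 1.75% of the Hcn1 UMIs and so could have given little of the excess. Wider forms of this class were not looked at for this. Different cluster shares remain a candidate explanation for part of the excess. The ratio of 1.13 became 0.80 with equal cluster weights, which lies between the values set in advance for and against. Within clusters 5 and 3 the ratio was 0.74 and 0.82, and whether the domain, the culture days or the single cultures set these was not tested.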
